A study of Mus musculus with 11 samples.

How the data were processed

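The data were 11 peak lists from CUT&RUN, an assay in which an antibody held on chromatin directs a nuclease to cut out the bound DNA for sequencing. Antibodies against WDR5 (a scaffold subunit of the MLL and SET1 histone methyltransferase complexes), P53 (the tumour suppressor transcription factor) and H3K4me3 (trimethylated lysine 4 of histone H3, a mark of active promoters) were used on mouse embryoid bodies at day 2. Per the labels' protocols, stem cells with a GFP reporter knocked into the Rx gene were differentiated by the SFEBq method in medium with 5% KSR, doxycycline was removed at day 0, 2% matrigel was added at day 1, and 2 µg of antibody was used for 2 M (mega) cells. The genotypes were wild type (WT), Wdr5 knockout (KO) and Wdr5 and p53 double knockout (DKO). WT and DKO had 2 lists each for WDR5 and for P53, and each genotype had 1 list for H3K4me3, which made 7 groups.

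Peaks were called by the authors with MACS 2.1.2 or 2.1.0.20150731 on paired-end fragments, without a control library, at a q cutoff of 0.01, with a local background of 10 kb and at most 2 fragments per position, per the file headers. The submitters' processing notes also named Bowtie2, SAMtools 1.5, bedtools, HOMER 4.10 and build mm10, with no role given for each. The pileup column is a coverage signal, the number of fragments over the summit and not scaled to depth, per the file headers. The -log10 p and -log10 q columns and the fold enrichment, a ratio of the pileup to the local background of the same library, are the authors' deposited values for each peak. They were used here to describe, rank or filter peaks within a list. Where values of several lists are given for a locus, they are not scaled to each other and were not tested against each other. Without a control library or a spike-in, regions with high background in any library can be called, and the number of peaks depends on depth and on the signal-to-background ratio of each library.

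Each list was called on its own alignment, but the headers of all 4 lists numbered 2 name an alignment merged from more than 1 run. In WT WDR5, 348 of the 450 summits of list 2 (77.3%) lay on the same base as a summit of list 1. The share was 80.3% in WT P53 and 75.3% in DKO WDR5, against 0.505% to 7.07% between lists of different antibodies or genotypes. Where the summits coincided, the pileup of list 2 was not higher in at least 99.2% of them, and list 2 held 0.905 to 0.925 of the fragments of list 1. These pairs therefore did not behave as separate libraries, and each was counted as 1 library (n = 1). In DKO P53, list 2 was deeper, and 19 of its 179 summits (10.6%) matched, so shared fragments were not shown there. As its alignment was also merged from runs, its independence was not established, and this group too was not counted as replicated. The exact permutation test planned for 2 against 2 lists, which cannot go below p = 0.333, was not read as a test. Bootstrap p-values for differences between KO and DKO cover the sampling of peaks or genes within 1 library of each, not the spread between libraries. Odds ratios and their p-values compare regions or genes within these libraries, not genotypes.

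From the lists, peaks on chromosomes 1 to 19, X and Y were kept, and the 35 peaks on the mitochondrial genome were left out. A region of WDR5 or P53 was a merged interval that overlapped a peak of both lists of its group by at least 1 base. It was taken as absent from DKO where it overlapped no peak of either DKO list of its antibody. Shares have Wilson 95% intervals, which cover counting error only. Fisher's exact test (two-sided) was used for tables of regions or genes. The Mantel-Haenszel odds ratio over 10 bins of WT fold enrichment was used for WT H3K4me3 peaks with and without WDR5. Positions were compared with 1000 seeded random placements on the same chromosome. Gene spans came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. That table gave no strand or exons, so the planned distance to a start site became the distance to either end of the gene span. Exons and introns were not analysed here. The window was 1 kb for WDR5 and H3K4me3 and 5 kb for P53.

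Before the data were examined, 12 gene lists with 434 entries were fixed, and all 434 matched a gene by symbol or by a synonym that a single gene has. They were p53 target genes, ribosomal protein genes, translation factor genes, pluripotency genes, anterior neural and eye field genes, mesoderm and endoderm genes, extraembryonic and trophoblast markers, fibroblast feeder markers, MLL and SET1 complex genes, replication dependent histone genes, mitochondrial and housekeeping genes, and cell cycle genes. The histone list also holds H3f3a, H3f3b, H2az1, H2ax and H1f0, which encode histone variants made outside S phase as well. The background was protein-coding genes with a WT H3K4me3 peak at an end, except for P53, where it was all protein-coding genes. P-values were adjusted by the Benjamini-Hochberg method over the 12 lists of a peak set. Named regions, also fixed beforehand, were the 20 WDR5 and the 20 P53 regions absent from DKO with the highest lower fold enrichment of the 2 lists, the 5 highest regions called in every list of the antibody, and the highest H3K4me3 peaks of each class. A gene was named for a region only within 10 kb. List members at bound regions were named as well, except that some ribosomal protein genes were left unnamed, in part because results for an item withheld for evaluation were left out.

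The overlap, list and stratified tests were tested on simulated data. Shifted copies of 5019 isolated WT H3K4me3 peaks were all found or all missed as constructed. Over 200 simulated draws on 7762 genes, a list of 70 genes with an odds ratio of 15 at a base share of 2.5% was called in 100% of draws, and a list of 30 genes with an odds ratio of 4 at a base share of 9% in 63%. Lists without enrichment were called in 0% of draws. On 9836 simulated peaks with an odds ratio of 2 and confounding by height, the stratified median was 2.03 and the crude median 2.68. The bootstrap of a difference between odds ratios called 8% of draws without a difference in a list of 30 genes, so it was slightly too ready to call. Alternatives covered a stricter list, the overlap rule, equal list lengths, all sequences, each list left out, other bins, windows, backgrounds and universes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.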

Results

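WDR5, P53 and H3K4me3 were profiled by CUT&RUN in day 2 embryoid bodies, aggregates of mouse embryonic stem cells directed towards anterior neural tissue, to compare their binding in WT, Wdr5 KO and Wdr5 p53 DKO cells. The lists rested on 26.6 M and 24.1 M fragments for WT WDR5, 26.4 M and 23.9 M for WT P53, 36.4 M and 33.7 M for DKO WDR5, and 32.8 M and 57.5 M for DKO P53. The H3K4me3 libraries held 34.2 M fragments in WT, 22.3 M in KO and 43.2 M in DKO. List 2 of WT WDR5, WT P53 and DKO WDR5 shared most of its summits with list 1 to the base, so each pair was counted as 1 library. List 2 of DKO P53 shared 10.6% of its summits with list 1, and whether it is a separate library was not established. No comparison had replicates in both genotypes, and the differences between genotypes have no replicate check. Coordinates are those of mm10.

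**Figure D1:**
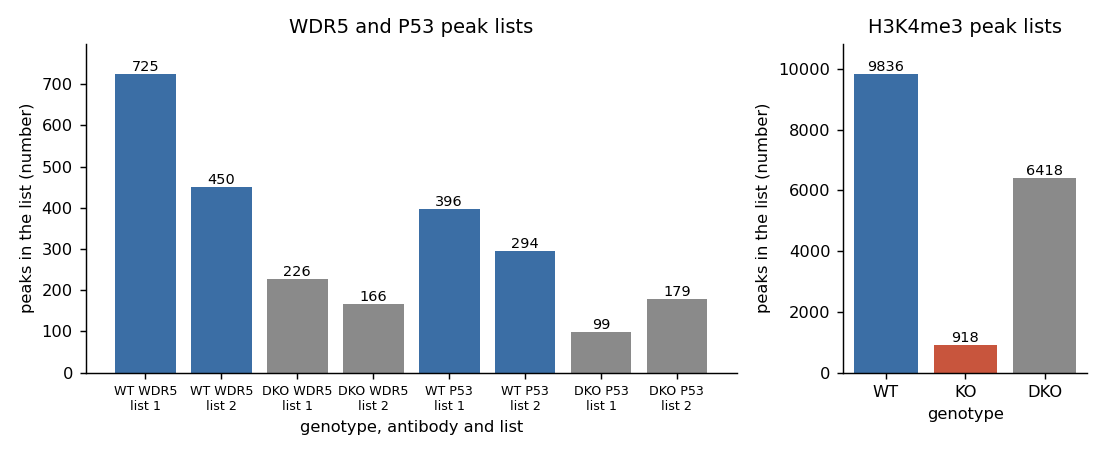
Number of peaks on chromosomes 1 to 19, X and Y in each list, with WDR5 and P53 lists on the left and H3K4me3 lists on the right; each bar is 1 list, coloured by genotype. WT WDR5 lists hold 725 and 450 peaks against 226 and 166 in DKO, and the H3K4me3 lists hold 9836 peaks in WT, 918 in KO and 6418 in DKO.

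At the targeted genes, no WDR5 or P53 peak lay within 10 kb of Wdr5 or Trp53 in any list. Wdr5 (chromosome 2, 27515147 to 27536535) had an H3K4me3 peak within 10 kb in all 3 genotypes, with a highest fold enrichment of 8.07 in WT, 4.66 in KO and 6.85 in DKO. Trp53, which encodes P53 (chromosome 11, 69580348 to 69591873), had one with 3.92, 4.04 and 3.51. H3K4me3 at these genes does not check the deletions, since the deleted parts are not given in the sources used here.

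WDR5 in WT lay mostly at the ends of genes, and ribosomal protein genes were the one fixed list at which its regions were enriched. The 19 ribosomal protein genes with a WDR5 region absent from DKO included Rpl7, Rpl11, Rpl23, Rpl27, Rpl32, Rpl37, Rps3, Rps14, Rps18 and Rps19, which encode proteins of both ribosomal subunits. The 19 made up 28.4% of the 67 list members marked by H3K4me3 in WT, against 2.47% of the 7695 other marked genes. None of the 79 list members had a region called in both DKO WDR5 lists. The odds ratio was 15.6 (95% interval 9.02 to 27.1, Fisher's exact test, adjusted p = 6.11e-14 over 12 lists).

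The highest of these was Rpl7, with a region on chromosome 1 from 16104039 to 16104763 that overlapped the gene's end, at a fold enrichment of 8.39 and 8.27 in the 2 lists. Rpl27 had 7.04 and 6.57, Rps14 6.85 and 6.00, and Rps3 6.57 and 6.80. Of the other lists, translation factor genes had 2 of 34 marked members at such a region (Fisher's exact test, adjusted p = 1), namely Eef1g, a subunit of elongation factor 1, and Eif3d, a subunit of initiation factor 3. The cell cycle list had 1 of 31 (Fisher's exact test, adjusted p = 1), E2f3, a transcription factor of S phase entry. Sesn1, a stress-induced sestrin among the p53 target genes, lay 616 bases from a WDR5 region but carried no H3K4me3 peak in WT. Pluripotency genes, anterior neural and eye field genes, mesoderm and endoderm genes, extraembryonic and trophoblast markers, fibroblast feeder markers, MLL and SET1 complex genes, replication dependent histone genes, and mitochondrial and housekeeping genes had 0 marked members at such a region. The largest of these lists had 22 marked members. With a share of 2.70% among the other marked genes, 0 would be usual for each, so it does not show that WDR5 avoids these genes.

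Among the 20 highest WDR5 regions absent from DKO, 15 lay within 1 kb of a gene end. They included regions at Tomm40, the import channel of the outer mitochondrial membrane (fold enrichment 8.68 and 8.03), at Ercc1, a nucleotide excision repair endonuclease subunit (8.39 and 7.52), at Tcf3, an E-protein transcription factor (7.32 and 7.41), and at Uvrag, an autophagy gene (7.30 and 6.78). The region on chromosome 7 from 27674653 to 27674968 overlapped an end of Zfp607b and lay 23 bases from Map3k10. The region on chromosome 6 from 85451471 to 85452458 spanned ends of both Pradc1 and Cct7, a chaperonin subunit, and that on chromosome 14 from 67715683 to 67716130 spanned ends of Cdca2 and Kctd9. Further members with a fold enrichment of at least 6.70 in both lists were at Zcchc7, Efcab12, E2f3, Evi5l, Rhpn2, Atxn7l2 and Iqch. Farther from an end were regions 3719 bases from Mid1, 3744 bases from Dus1l and 4208 bases from the end of Gm38510. The Mid1 region overlapped an H3K4me3 peak in WT, KO and DKO. It also overlapped a WT P53 region that was not among those absent from DKO, so it may be a place called without the target. The 2 highest regions had no gene within 10 kb.

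WT WDR5 lists held 725 and 450 peaks, and DKO lists held 226 and 166, a log2 ratio of the means of 1.58. Of 438 WDR5 regions called in both WT lists, 312 (71.2%, 95% interval 66.8 to 75.3) were absent from DKO although the DKO lists were deeper. Without WT WDR5 list 2, the number absent from DKO was 580 of 725. In reverse, a peak of WT list 1 overlapped 62.8% of the peaks of DKO list 1 and 69.9% of those of DKO list 2. Peaks called in cells labelled as lacking WDR5 were thus often absent from WT too, so absence from DKO alone does not show that a region depends on WDR5. Of the 312 regions, 192 (61.5%) lay within 1 kb of a gene end, and 124 (39.7%, 34.5 to 45.3) overlapped a WT H3K4me3 peak, against at most 7 in 1000 random placements. That last share was 7.50% with lists of equal length, which keep the highest regions, and 62.4% when regions within 500 bases counted as shared. The DKO lists themselves held 160 regions called in both, of which 43.1% lay at a gene end and 76.3% overlapped a WT H3K4me3 peak. The highest region called in all 4 WDR5 lists, on chromosome 6 from 103648781 to 103649292 inside Chl1, had a fold enrichment of 42.5 and 38.2 in WT and 43.7 and 39.1 in DKO. A region at Lars2, a mitochondrial leucyl-tRNA synthetase, had 34.5 and 32.9 in WT and 32.7 and 30.8 in DKO.

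**Figure D2:**
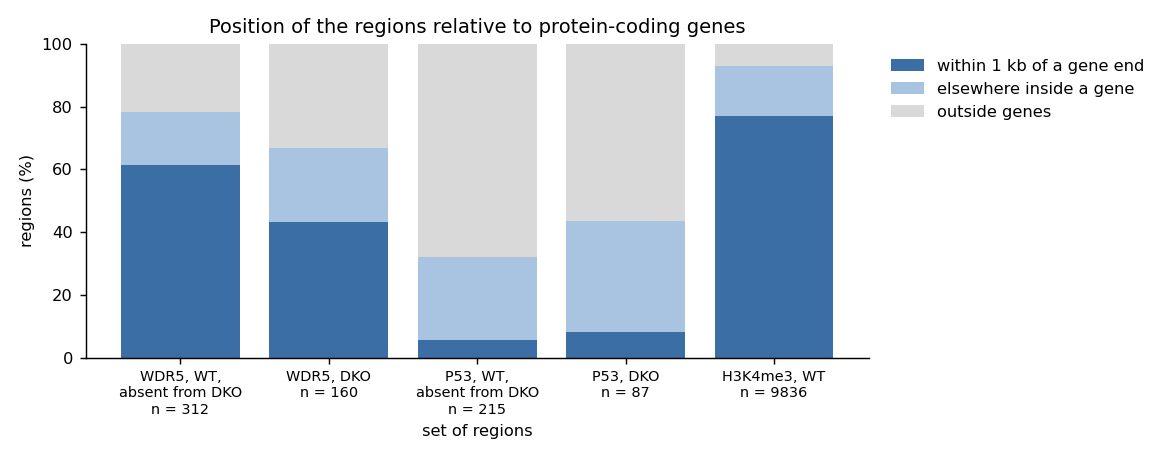
Share of regions, in percent, within 1 kb of an end of a protein-coding gene, elsewhere inside a gene, or outside genes, for each set of regions named under the bars with its number. WDR5 regions absent from DKO lay at a gene end in 61.5% and P53 regions absent from DKO in 5.58%.

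P53 in WT lay mostly outside genes and away from H3K4me3, and p53 target genes were the one fixed list at which its regions were enriched. Regions absent from DKO lay within 5 kb of an end of Bbc3, which encodes the pro-apoptotic protein PUMA, Zmat3, an RNA-binding zinc finger gene, Plk2, a polo-like kinase gene, and Eda2r, a receptor gene of the TNF receptor family. These were 4 of 40 list members (10%) against 0.169% of the 21847 other genes, an odds ratio of 65.5 (22.2 to 193, Fisher's exact test, adjusted p = 1.11e-05). None of the 40 list members lay near one of the 87 P53 regions called in both DKO lists. Each of the other 11 lists had 0 members near a P53 region absent from DKO (Fisher's exact test, adjusted p = 1). With so low a share among all genes, 0 members would be usual for lists of this size. The odds ratio was 27.5 when the whole gene span counted with the 5 kb, an alternative chosen after the data were seen, and 197 with a window of 1 kb. Against marked genes only, 1 member was left and the call ended (odds ratio 24.0, Fisher's exact test, adjusted p = 0.545).

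The Bbc3 region, on chromosome 7 from 16308453 to 16309305, lay inside the gene 55 bases from its end, with a fold enrichment of 12.8 and 11.7. The Zmat3 region, on chromosome 3 from 32363998 to 32364710, lay inside the gene with 8.95 and 8.35. The Plk2 region lay 2084 bases outside the gene on chromosome 13, from 110392459 to 110392960, with 7.79 and 7.36. The Eda2r region, on chromosome X from 97376690 to 97377043, had 4.78 and 4.67. List 1 alone, without list 2, added 3 members, for 7 in all: Cdkn1a, which encodes the cell cycle inhibitor p21, at 65 bases with a fold enrichment of 4.76, Aen, an apoptosis nuclease gene, with a region inside the gene at 5.28, and Trp53inp1 at 1009 bases and 4.45. These 3 were named after their values were seen.

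Among the 20 highest P53 regions absent from DKO, Bbc3 was the one within 1 kb of a gene end, and 7 had a gene within 10 kb. The others of these were Zfp809, a retroviral silencing gene (fold enrichment 13.8 and 13.2, 1278 bases inside), Npl (13.7 and 12.9), Lemd1 (13.0 and 12.1), Rims1 (13.2 and 11.9), Nrg1, a neuregulin gene (11.6 and 10.8), and Zfp945 (11.4 and 10.6). A region on chromosome 4 from 133900168 to 133900620, 12371 bases from Rps6ka1, reached 22.6 and 20.7. Regions inside Cemip2, on chromosome 19 from 21790959 to 21791807, and inside Mtmr10, on chromosome 7 from 64327214 to 64327641, reached at least 14.2 and 13.5 in both lists. The highest of the 20, at 38.5 and 34.5, was the Chl1 region that was also called in all 4 WDR5 lists, DKO included.

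WT P53 lists held 396 and 294 peaks and DKO lists 99 and 179, a log2 ratio of the means of 1.31. A peak of WT list 1 overlapped 68.7% of the peaks of DKO list 1 and 45.8% of those of DKO list 2. Many peaks called in cells labelled as lacking P53 were thus absent from WT, so absence from DKO alone does not show that a region depends on P53. Of 288 P53 regions called in both WT lists, 215 (74.7%, 69.3 to 79.3) were absent from DKO. Of these, 12 (5.58%) lay within 1 kb of a gene end and 146 (67.9%) lay outside genes, and the median distance to an end was 20309 bases. WDR5 regions lay at an end far more often (odds ratio 27.1, 14.5 to 50.6, Fisher's exact test, p = 7.30e-44). A WT H3K4me3 peak overlapped 13 P53 regions (6.05%, 3.57 to 10.1), against at most 5 in 1000 random placements. That share was 9.09% without DKO P53 list 2, 0.901% in the top 50% of each list by fold enrichment and 1.64% with lists of equal length. A KO H3K4me3 peak overlapped 11 of the 215 regions (5.12%), although the KO list held 918 peaks against 9836 in WT. Random placement does not allow for places called in many libraries, so it does not show P53 at promoters marked in WT. The 87 P53 regions called in both DKO lists also lay mostly outside genes (56.3%), with 8.05% at a gene end. Position relative to genes thus did not set the WT regions apart, while 81.6% of the DKO regions overlapped a WT H3K4me3 peak. The highest region called in all 4 P53 lists, on chromosome 9 from 35305230 to 35305578, had 26.3 and 26.3 in WT and 27.3 and 27.4 in DKO.

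The shared occupancy of WDR5 and P53 was asked at WT H3K4me3 peaks. In WT, 42 of the 9836 peaks carried a region of both, and the odds ratio was 75.8 (46.4 to 124, Fisher's exact test, p = 6.23e-52). Its size depended on the regions compared, with 5.78 (4.16 to 8.03) over all regions called in any library and 987 in the top 50% of each list. In DKO, whose cells are labelled as lacking both proteins, 55 peaks carried both, with an odds ratio of 539 (290 to 1002, Fisher's exact test, p = 2.80e-97), which was 211 (133 to 335) without DKO P53 list 1 and 267 over all regions called in any library. With only regions absent from DKO, 1 peak carried both (6.57, 0.848 to 50.9, Fisher's exact test, p = 0.152). Directly, 50 of 438 WDR5 regions overlapped a P53 region in WT, and 3 of the 312 absent from DKO overlapped a P53 region that was also absent from DKO. At Sp1, a zinc finger transcription factor gene, the WDR5 region on chromosome 15 from 102405724 to 102406203 (fold enrichment 6.00 and 6.47) lay inside a P53 region (5.94 and 5.69), away from H3K4me3. Another of the 3 lay 787 bases from Rap2b, a small GTPase gene, also away from H3K4me3. Among the DKO regions, 61 of 160 WDR5 regions overlapped a P53 region.

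H3K4me3 was called at far fewer genes in the KO library than in WT, and at an intermediate number in DKO. A peak lay within 1 kb of an end of 7762 protein-coding genes in WT, 701 in KO and 4999 in DKO. In KO the mark was called at 24 of the 67 ribosomal protein genes marked in WT, such as Rpl5, Rpl7 and Rps9. It was also called at 11 of 34 translation factor genes, such as Eef2 and Eif4g2, 9 of 31 cell cycle genes, such as Pcna, Cdk1 and Cdk4, and 7 of 24 p53 target genes. Each of these 4 lists was above the 8.75% to 8.92% of the other marked genes.

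**Figure D3:**
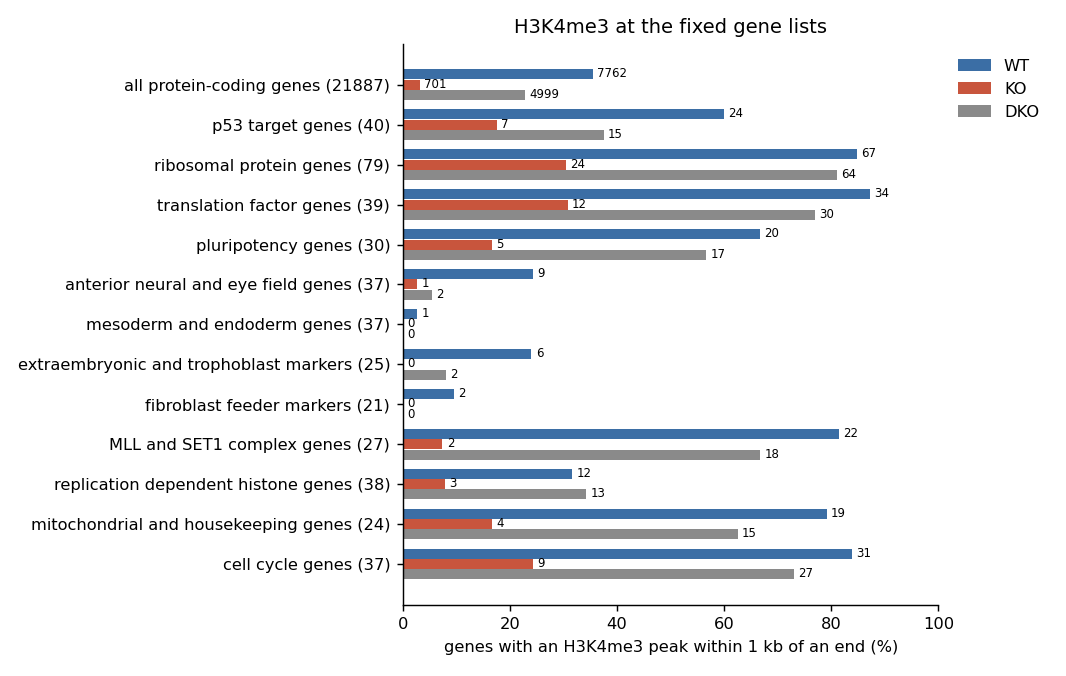
Share of the genes of each fixed list, in percent, with an H3K4me3 peak within 1 kb of an end in WT, KO and DKO; the number of members is in brackets and the number of genes with a peak stands at each bar. Of 79 ribosomal protein genes, 67 had a peak in WT, 24 in KO and 64 in DKO.

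By Fisher's exact test over 12 lists, the odds ratios in KO were 5.82 for ribosomal protein genes (3.51 to 9.66, adjusted p = 1.45e-08), 4.91 for translation factor genes (adjusted p = 0.000707), 4.19 for cell cycle genes (adjusted p = 0.00476) and 4.21 for p53 target genes (1.74 to 10.2, adjusted p = 0.0122). The 7 p53 target genes were Mdm2, the ubiquitin ligase that degrades P53, Ccng1, Apaf1, a core part of the apoptosome, Phlda3, Sesn2, Polk and Gtse1. In the KO list, their fold enrichment was 5.08 at Mdm2, 5.07 at Apaf1, 4.36 at Phlda3, 4.27 at Sesn2, 4.02 at Polk, 3.81 at Gtse1 and 3.73 at Ccng1. Apaf1 and Phlda3 had no peak in DKO. In the top 50% of each list, 2 lists passed in KO and 1 in DKO, and the p53 target genes (odds ratio 1.16, Fisher's exact test, adjusted p = 1) and translation factor genes (1.68, adjusted p = 0.855) lost their call in KO.

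In DKO, ribosomal protein genes (60 of 67, odds ratio 5.84, adjusted p = 1.26e-06), translation factor genes (29 of 34, 3.92, adjusted p = 0.0140) and cell cycle genes (26 of 31, 3.52, adjusted p = 0.0217) exceeded the other marked genes by Fisher's exact test. In the top 50% of each list, translation factor genes (2.49, Fisher's exact test, adjusted p = 0.428) and cell cycle genes (1.73, adjusted p = 0.825) lost that call. The p53 target genes, at 15 of 24, did not pass (1.12, 0.491 to 2.57, Fisher's exact test, adjusted p = 0.838). Pluripotency genes were called at 20 of 30 in WT, and of these 5 were called in KO (adjusted p = 0.0687) and 16 in DKO (Fisher's exact test, adjusted p = 0.169). Within 10 bins of WT height, an alternative chosen after the data were seen, pluripotency genes passed in KO (odds ratio 3.81, 1.41 to 10.3). The 5 were Pou5f1, Sox2, Utf1, Tet1 and Pou3f1. Pou5f1, which encodes OCT4, had a fold enrichment of 4.85 in WT, 4.64 in KO and 4.93 in DKO.

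Anterior neural and eye field genes with a peak in WT were Otx2, Six6, Zic2, Zic5, Tcf7l1, Gbx2, Irx3, Sox11 and Hes1, 9 of 37. Of these, Zic2 was called in KO (adjusted p = 0.857), and Otx2 and Tcf7l1 in DKO (22.2% against 59.8% of the other marked genes, Fisher's exact test, adjusted p = 0.107). Rax, the gene of the reporter, had no peak in any library. The markers of other tissues with a peak in WT were Eomes of 37 mesoderm and endoderm genes, Col5a1 and Thy1 of 21 fibroblast feeder markers, and 6 of 25 extraembryonic and trophoblast markers, which were Krt8, Krt18, Lamc1, Col4a1, Col4a2 and Apoa1. None of them was called in KO, and Krt18 and Lamc1 were called in DKO, with no list passing Fisher's exact test (lowest adjusted p = 0.243). Of 22 marked MLL and SET1 complex genes, Wdr5 and Hcfc1 were called in KO and 17 in DKO. Replication dependent histone genes were called at 3 of 12 in KO (H3f3a, H2ax and H2az1, histone variant genes) and 6 of 12 in DKO, and mitochondrial and housekeeping genes at 4 of 19 in KO and 15 of 19 in DKO, with no call for these 3 lists. Within bins of WT height, histone genes passed in KO (odds ratio 7.86, 1.87 to 33.1), and housekeeping genes passed in KO (4.21, 1.34 to 13.3) and DKO (3.77, 1.19 to 11.9).

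Of the 9836 WT H3K4me3 peaks, 795 (8.08%, 7.56 to 8.64) overlapped a KO peak and 4837 (49.2%, 48.2 to 50.2) a DKO peak. All 3 libraries shared 699, WT and DKO alone shared 4138, and 4903 were called in WT alone. Higher WT peaks were mostly called again more often. In KO the share was 3.46% in the lowest bin of WT fold enrichment, 1.42% and 2.34% in bins 2 and 3, and 24.5% in the highest. In DKO it went from 25.1% in the lowest bin to 84.8% in the highest. The highest named peaks called in WT alone were at Emc7 (fold enrichment 9.25), Chpt1 (8.31) and Nadsyn1 (8.26). Lists of equal length keep the 918 peaks with the highest fold enrichment of each library. Of these WT peaks, 24.7% overlapped a KO peak and 37.7% a DKO peak, shares of a different set from the 9836. With 1 library per genotype and no spike-in, a change in the mark and a change in library quality give the same lists.

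**Figure D4:**
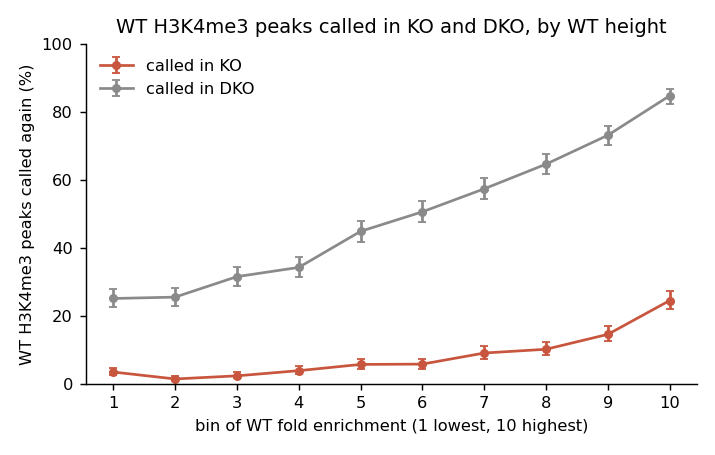
Share of WT H3K4me3 peaks, in percent, called again in KO and in DKO, by bin of WT fold enrichment from 1 (lowest) to 10 (highest); points are shares of 983 or 984 peaks and bars are Wilson 95% intervals. The share rose to 24.5% in KO and 84.8% in DKO in the highest bin.

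WT H3K4me3 peaks that carried a WDR5 region were called again more often than the others in both knockouts. In KO, 62 of 219 (28.3%) were called again against 7.62% of the 9617 others, a Mantel-Haenszel odds ratio within 10 bins of WT height of 3.71 (2.68 to 5.13, n = 219 peaks, p = 3.18e-17). The excess in KO was uneven across bins. Bin 10, the highest, gave 32 of the 62, from 53 peaks with WDR5, against 24.5% of all its peaks. Bin 1 gave 7 of 29 against 3.46%, while bin 9 gave 3 of 28 against 14.5%, with no excess. In DKO, 155 of 219 (70.8%) were called again against 48.7%, with an odds ratio of 2.15 (1.56 to 2.97, n = 219 peaks, p = 1.30e-06). With only the 124 peaks whose WDR5 region was absent from DKO, 20 were called again in KO (odds ratio 1.95, n = 124 peaks, p = 0.00673) and 78 in DKO (1.65, p = 0.0112).

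KO peaks that were not in WT lay mostly away from gene ends, with 76 of 114 (66.7%) outside genes and 31 elsewhere inside a gene. Of 918 KO peaks, 114 overlapped no WT peak, and 7 of these (6.14%) lay within 1 kb of a gene end against 70.1% of the 804 that did (odds ratio 35.9, 16.5 to 78.3, Fisher's exact test, p = 1.51e-41). The highest was on chromosome 5 from 27987068 to 27987382, outside genes, with a fold enrichment of 10.4. In DKO, 1406 of 6418 peaks overlapped no WT peak, of which 51.4% lay at a gene end against 79.2% of the others (odds ratio 3.60, 3.18 to 4.08, Fisher's exact test, p = 6.94e-89). The 3 highest of them lay on chromosome 8 between 19727885 and 20389649, with 9.81, 8.93 and 8.17.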

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

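Chosen only after the result was seen were the bootstrap for peaks with WDR5, the share of the strongest WT peaks, the area under the curve, the overlap with DKO regions, absence from all 4 DKO lists, the bins of WT height for p53 target genes and the count at genes with a P53 region. In these single libraries of KO and DKO, the log2 odds ratio for WT H3K4me3 peaks with a WDR5 region against the others to be called again was 0.78 higher in KO within bins of WT height (95% interval 0.18 to 1.36, bootstrap over peaks, n = 219 with WDR5, p = 0.012, 1000 resamples). With only WDR5 regions absent from DKO, the difference was 0.24 (-0.72 to 0.97, n = 124 with WDR5, p = 0.62). Both p-values cover the sampling of peaks only, not the spread between libraries.

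The KO library held fewer H3K4me3 peaks than WT and DKO. Lower depth as the whole cause would leave the strongest WT peaks called, but of the 918 WT peaks with the highest -log10 q, KO called 300 (32.7%, 29.7 to 35.8) and DKO 836 (91.1%), so depth alone is unlikely. Weaker enrichment in the KO library may still account for it. The area under the curve of WT fold enrichment for peaks called again in KO was 0.731 (0.713 to 0.750), and 0.725 in DKO, which does not separate a weaker library from a loss of the mark. Loss of WDR5 as the biological explanation stays open, since there was 1 library per genotype and no spike-in.

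WDR5 and P53 regions coincided on 42 WT H3K4me3 peaks. All 42 (100%, 91.6 to 100) overlapped a region called in a DKO WDR5 or P53 list, against 1.97% of all WT H3K4me3 peaks. Most of all those peaks carried neither region, so they are not a like set. Of the 219 WT peaks with a WDR5 region, 124 had one absent from DKO, so overlap with DKO regions was also frequent among peaks chosen for WDR5 alone. The coincidence may thus come from regions that CUT&RUN yields without the target protein. With only regions absent from DKO, the odds ratio was 6.57 (0.848 to 50.9), an interval too wide to tell whether a coincidence remains. On H3K4me3 peaks, 1 carried both regions absent from their own DKO lists, and 0 did when absence from all 4 DKO lists was asked. The stricter rule can only remove regions, so that 0 adds no test. Joint binding away from H3K4me3 stays open, as the pairs at Sp1 and Rap2b lay outside these peaks.

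The p53 target genes exceeded other marked genes in KO, where p53 is not deleted per the labels, and did not pass in DKO. Higher WT peaks at these genes are unlikely as the whole cause, since the odds ratio within 10 bins of WT height was 4.12 (1.59 to 10.7). Within these bins 7 of the 12 lists passed in KO, so an excess in KO was not particular to p53 target genes. The difference between KO and DKO was 1.99 on the log2 scale (0.22 to 3.46, bootstrap over list members, n = 24 genes, p = 0.0358), and after adjustment over the 8 lists with at least 10 marked genes p was 0.241, so a chance difference stays open. The histone list had a larger difference, 2.48 (-0.28 to 4.39, bootstrap over list members, n = 12 genes, p = 0.0602), with the same adjusted p. Of the 4 p53 target genes with a P53 region, Zmat3 alone was marked in WT, and it was not called in KO (0%, 0 to 79.3, n = 1), too few to tell whether P53 binding goes with the calls. A P53-dependent mark thus may or may not be present, and 1 library per genotype cannot decide it.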

How the results depend on the processing

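Alternatives added after the data were seen were the absence from all 4 DKO lists, the gene span with 5 kb for P53, and the bins of WT height for lists kept in KO and DKO. Of 185 values under an alternative, 157 kept their call or stayed within the set range, 21 moved, 6 lost their call, and 1 reversed. The enrichment of ribosomal protein genes at WDR5 regions held under all 9 alternatives run (odds ratio 11.5 to 30.2), and the more frequent calls at WDR5-bound peaks under all 10 (1.95 to 5.24 in KO, 1.65 to 4.39 in DKO). These alternatives are not independent checks. For ribosomal protein genes, all sequences, absence from all 4 DKO lists and DKO WDR5 list 2 left out each gave the same 15.6 with 19 genes. The 2 WT WDR5 lists, each left out in turn, were counted as 1 library. The strict list was void for peak numbers, which it divides by the same factor.

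In the top 50% by fold enrichment, WDR5 regions at H3K4me3 were 30.2%, P53 regions 0.901%, WT peaks called in KO 6.93% and in DKO 44.5%, and 2 lists passed in KO and 1 in DKO. With 50% of the shorter region overlapping, WDR5 regions at H3K4me3 were 33.3% and peaks called in DKO 46.1%. With 500 bases allowed, they were 62.4% and 54.2%, and those called in KO 8.89%. Lists of equal length gave 55.6% of WDR5 and 68.5% of P53 regions absent from DKO, with 7.50% and 1.64% of these at H3K4me3. Of the 918 highest WT peaks kept in that setting, 24.7% were called in KO and 37.7% in DKO, and co-occupancy in WT was not finite. WDR5 and P53 co-occupancy fell to 6.57 with regions absent from DKO, and to 0 with regions absent from all 4 DKO lists, by removal of the shared regions. That 0 was counted as the 1 reversal because it lies below 1, but it does not show that the proteins avoid each other. With marked genes as the background, 0 lists passed for P53 (p53 target genes 24.0), because 3 of the 4 genes were not marked. Within bins of the highest WT peak, 7 lists passed in KO, with pluripotency, histone and housekeeping genes added, and 4 in DKO, with housekeeping genes added. The cause was not tested for the other shifts.

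Leaving out each list in turn gave 71.3% to 80% of WDR5 and 74.7% to 80.2% of P53 regions absent from DKO. With the list number as a block, the log2 ratios of peak numbers were 1.56 for WDR5 and 1.36 for P53; the numbers do not pair the libraries beyond a shared label, and neither ratio was tested. The depth of 22.3 M fragments in KO limits what its list can show.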

Other observations

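These tests were chosen after the data were seen, except the overlap of KO peaks with P53 regions. In DKO, H3K4me3 was called at 7 of the 26 genes of the histone list that had no peak in WT (26.9% against 2.51% of the 14099 other unmarked genes, odds ratio 14.3, 5.98 to 34.2, Fisher's exact test, adjusted p = 3.49e-05 over 12 lists). They were H2ac18 and H3c13 on chromosome 3 and H2bc7, H3c4, H3c3, H2ac4 and H3c2 on chromosome 13, and they shared 6 peaks with a fold enrichment of 3.17 to 3.85, because neighbours can share a peak. Fisher's exact test also gave 4 of 12 unmarked ribosomal protein genes, Rps15a, Rplp1, Rpl10a and Rps28 (odds ratio 19.3, 12 lists, adjusted p = 0.00106). Nanog, Ccne2, Nop56 and Kat8 were also called in DKO and not in WT. In KO, 1 of 5 unmarked translation factor genes, Eif4a1, was called (Fisher's exact test, odds ratio 1176, adjusted p = 0.0170), a call that rests on 1 gene. The DKO library was deeper than the WT library.

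Gene families formed by symbol were tested in the same way, and their Rpl and Rps genes at WDR5 are the same 19 genes as in the fixed list. A family took every symbol with the same letters before its first digit. Rps thus also took in symbols such as Rps6ka1, which is not in the list of ribosomal protein genes. The Rpl and Rps shares below are therefore not those of ribosomal protein genes alone, which were called at 24 of 67 in KO and 60 of 67 in DKO. Among 165 families with at least 10 genes and 5 marked ones, Rpl genes had a WDR5 region at 13 of 41 (odds ratio 17.8, adjusted p = 4.03e-09, Fisher's exact test) and Rps genes at 6 of 30 (9.27, adjusted p = 0.0101). Zfp genes, which encode zinc finger proteins, had one at 4 of 209 (Fisher's exact test, adjusted p = 1). In DKO, H3K4me3 was called at 38 of 43 marked Eif genes (Fisher's exact test, adjusted p = 0.00993), 36 of 41 Rpl genes (adjusted p = 0.0130) and 23 of 25 Ddx genes, which encode RNA helicases (adjusted p = 0.0285), against 59.6% of the others, while Rps genes, at 24 of 30, did not pass (adjusted p = 0.276). In KO, Rpl genes passed at 14 of 41 (Fisher's exact test, adjusted p = 0.00114), and Rps genes at 9 of 30 (adjusted p = 0.0756) and Eif genes at 10 of 43 (adjusted p = 0.164) did not. In DKO, the mark was called at 0 of 8 marked Stx genes, which encode syntaxins (Fisher's exact test, adjusted p = 0.0285), and at 0 of 6 Fzd and 0 of 6 Sema genes, which encode Wnt receptors and semaphorins (adjusted p = 0.0999 for each).

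A hypothesis that the KO peaks outside WT mark P53-bound sites was tested by overlap. Of the 114, 2 (1.75%, 0.482 to 6.17) overlapped a WT P53 region absent from DKO, against 9 of the 804 KO peaks shared with WT. Sites called for P53 in WT are thus unlikely to be their source. P53 was not profiled in the KO cells, so sites that it binds only there could not be tested. Of the 114, 10 were called in DKO and 6 overlapped a DKO WDR5 or P53 peak.

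The Chl1 region on chromosome 6, among the highest in both WDR5 genotypes and in WT P53, was called in H3K4me3 of WT and DKO, and in neither DKO P53 list nor KO H3K4me3.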
